A study of Rattus norvegicus with 36 samples.

How the data were processed

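Total RNA from the lung of male CDF F344 rats was measured on 36 Illumina rat BeadChip arrays, 1 array per rat. Per the labels, the rats were 3 months old and inhaled crystalline silica at 15 mg/m3 or air for 6 h per day on 5 days per week. Exposure lasted 3, 6 or 12 weeks, which with the 2 treatments gave 6 groups of 6 rats, and each week had its own air group. The labels give an RNA input of 375 ng per labelling and a number for each rat. They do not say which arrays shared a chip, and the time of day of necropsy was not given in the sources used here.

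The deposited non-normalised table gives the mean bead intensity of each probe on each array, and per the file headers a detection p-value of the probe stands beside it. The intensity values carried no background subtraction, since none was negative and the array medians differed. A second deposited table holds log2 values that the authors had processed. Their distributions were nearly equal on all arrays, with medians from 7.10 to 7.12, and their slope against the log2 of the raw intensity was 0.254 for the dimmest and 0.991 for the bright probes. The submitters' processing notes name BeadStudio, lumi and limma without versions or settings, so the transformation behind the authors' log2 values is not known. For a match of columns, the mean of each probe over the arrays was subtracted from the log2 values of both tables. Each of the 36 columns of the authors' table then had its best correlation with the raw column of the same sample. These ran from r = 0.705 to 0.931 across probes, which are not independent replicates.

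The table held 21792 probes. A gene symbol came from the rat RefSeq gene table for 13349 probes through the Entrez gene number of the array annotation and for 5 through an accession, and 34 kept the symbol printed on the array. The other 8404 probes had no symbol here, and none had several. The 13388 probes with a symbol stood for 13315 genes. A probe was taken as detected when its detection p lay under 0.05 on at least 6 arrays, which 12622 probes met, 9097 of them with a symbol. Of several detected probes of 1 gene, which occurred for 19 genes, the one with the highest mean level was used. This left 9078 genes for testing, while the 3525 detected probes without a symbol were fitted apart.

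Background correction, between-array quantile normalisation and the log2 transformation followed the neqc procedure of limma with an offset of 16. It models each signal as background plus exponential signal and takes the mean and SD of the background from the detection p-values. The detection p-values lay on a grid of steps of 1 over 825, the number of negative-control probes that the grid implies, for 21204 probes. For the other 588 probes they lay off that grid, and including these gave a median background mean of 73.5 and SD of 154 against 47.3 and 8.59 without them. The background was therefore inferred from the probes on the grid and applied to all probes. This departs from the plain neqc call, and it was chosen after the data had been examined and after the gene counts under both versions had been seen. The version from all probes is reported beside the main counts, and 179 tested genes came from probes off the grid.

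All 36 arrays entered 1 linear model with 6 group means in limma 3.58.1 under R 4.3.3, which left 30 residual degrees of freedom, and all tests were two-sided moderated tests. Silica was compared with the air group of the same week at 3, 6 and 12 weeks. Differences of the silica effect between weeks were tested as contrasts of these contrasts, and the air groups were compared with each other by an F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes of a comparison, and a second count also asked for a change of at least 1.5-fold. Genes called at all 3 weeks were set against the product of the shares of called genes. Log2 changes are silica minus air and carry the standard error (SE) of the model, and every group had n = 6.

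Gene lists fixed before the data were examined covered 18 pathways and 18 cell types, the latter including tissues that a piece of lung can carry along. The pathway lists were chemokines, acute phase and secreted innate defence proteins, complement, IL-1, TNF and NF-kB signalling, NRF2 targets and antioxidant enzymes, NADPH oxidase and nitric oxide synthesis, collagens and matrix proteins, matrix proteases and inhibitors, lysosome, surfactant proteins and lipid secretion, cholesterol synthesis and uptake, cell cycle and DNA replication, antigen presentation by MHC class II, interferon response, p53 targets and apoptosis, xenobiotic and airway metabolism, circadian clock, and oxidative phosphorylation. The cell type lists were neutrophils, alveolar macrophages, monocytes and dendritic cells, type II and type I pneumocytes, club and secretory cells, ciliated cells, endothelial cells, fibroblasts, smooth muscle, T and NK cells, B and plasma cells, mast cells, red cells, heart muscle, adipose tissue, thymus and lymphoid organ, and mesothelium. Lists share members, and 9 of the 15 measured type II pneumocyte genes are also in the surfactant list. Each list was tested at each week with camera, which compares its genes with all other genes, at a preset correlation between genes of 0.01. The same test with the correlation estimated from the data and the fry test, which asks whether the genes of a list change at all, were run beside it. Ranges of the adjusted p of a list over the alternatives leave these 2 tests out. Adjustment covered all lists and all 3 weeks. Members called over all genes are counted for each list, with the count adjusted over the list alone beside it.

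Named genes followed a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls at each week among called genes whose 6 silica arrays all lie beyond all 6 air arrays. It also takes up to 4 called members per described list with the largest change, the 5 largest positive and 5 largest negative called differences between weeks, and the 5 genes with the smallest adjusted p across the air groups. The list members printed are a part of what the rule allows, and this part was chosen after their values were seen, as were the genes in the plots. Where no array of a group detected a gene, the fold is a lower bound. On each array of the undetected group the gene was set to the lowest level of any detected probe, or to its own level where this was higher, and the mean of these was subtracted from the mean of the other group.

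The pipeline after normalisation was tested on simulated log2 levels with the group sizes and the spread of the real arrays. At 3 weeks, over 9078 genes, it recovered 58% of genes with a log2 change of 0.25, 94% with 0.5 and 100% with 1 or 2. For the difference between 12 and 3 weeks it recovered 28%, 74%, 100% and 100% of the same sizes. It made 5 calls among 8878 unchanged genes at 3 weeks and 0 at 6 weeks, where no change was simulated. All 6 shifted lists were called and 0 of 22 lists without a shifted gene. The simulated genes varied independently of each other, so these list counts cannot test the preset correlation between genes. For the same reason the gene counts do not show how shifts shared by many genes of an array affect false calls. Background correction, normalisation, the detection filter and the choice of probe were not simulated.

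Alternatives fixed before the data were examined were no background correction, median scaling in place of quantile normalisation, the authors' processed values, no detection filter, a stricter filter of detection p under 0.01 on at least 18 arrays, the mean of the detected probes of a gene, only the arrays of the weeks compared, an intensity trend with robust variance, array weights, a replicate number block, an adjusted p under 0.01, the estimated list correlation, fry, and leaving out each array in turn. Alternatives added after seeing the data were the background from all probes, leaving out the probes off the grid, and leaving out 2 arrays that stood apart from their groups. The counts of called genes and lists were also recomputed for 100 splits of the arrays, the real one included. Relations across rats were given with permutation tests, and differences of list means between 6 silica and 6 air rats with exact permutation tests over 924 splits. The replicate number block paired the silica and the air rat of the same week and replicate number. A chip block was not run because the labels give no chip.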

Results

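Lung RNA was measured on 36 arrays from rats that inhaled crystalline silica at 15 mg/m3 or air, with 6 rats in each of the 6 groups at 3, 6 and 12 weeks. The comparisons ask how gene expression in the lung responds to sub-chronic inhalation of crystalline silica, a mineral dust that causes lung inflammation and scarring, and how the response changes with the length of exposure. The mean raw intensity per array ran from 345 to 519 and the median from 52.0 to 66.7. Between 48.7% and 53.1% of probes were detected on an array. The number of arrays per group limits the precision of every value.

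The first principal component held 54.5% of the variance of the log2 levels and set the 12 arrays of the 6-week set, at 22.7 to 29.8, apart from nearly all others. Silica and air arrays of that week lay together on it, and the labels give no array batch, so week and batch cannot be told apart. The second component held 11.4%. The 3-week and 12-week arrays lay between -25.0 and -8.10, except that air replicate 5 at 3 weeks lay at 8.72 and silica replicate 3 at 12 weeks at 15.1.

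**Figure D1:**
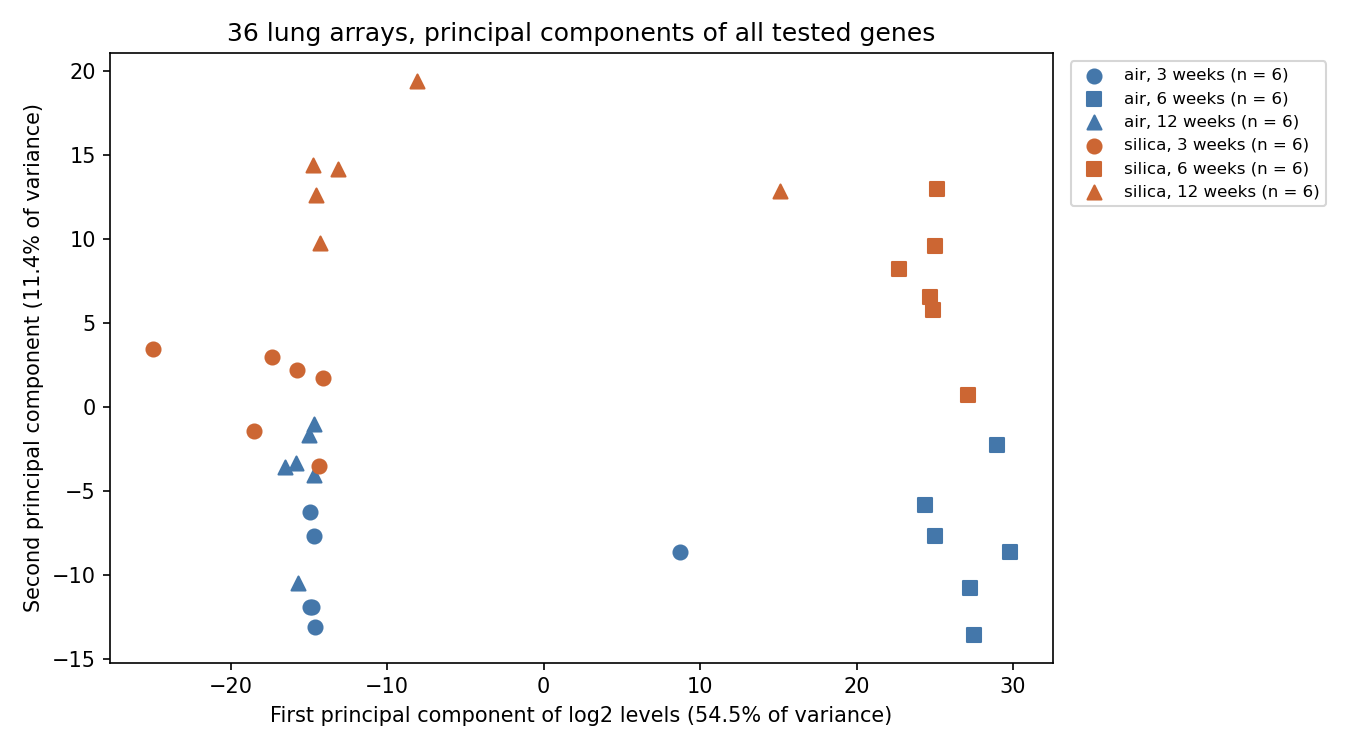
First (horizontal) and second (vertical) principal component of the log2 levels of all tested genes, 1 point per array, coloured by treatment and shaped by week (n = 6 per group). The 12 arrays of the 6-week set lie at 22.7 to 29.8 on the first component, and air replicate 5 at 3 weeks (8.72) and silica replicate 3 at 12 weeks (15.1) lie between them and their own groups.

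Among named genes whose groups did not overlap, the largest rises after 3 weeks of silica were those of Slc26a4, Mmp12 and Lcn2. Slc26a4, which encodes the anion exchanger pendrin, rose 5.13-fold (log2 2.36 ± 0.32, SE, n = 6 per group, adjusted p = 5.04e-06). Mmp12, the macrophage metalloelastase, rose 4.35-fold (2.12 ± 0.29), and Lcn2, which binds bacterial siderophores, rose 3.66-fold (1.87 ± 0.27). The ribonuclease-family gene Rnase9 rose 3.45-fold (1.79 ± 0.10), Noxo1, an organiser subunit of NADPH oxidase, 3.00-fold (1.59 ± 0.17), Tmem45b 2.90-fold (1.54 ± 0.11) and the resistin-like gene Retnla 2.57-fold (1.36 ± 0.25). Nr1d1, which encodes the clock repressor REV-ERB alpha, was 5.06-fold lower (log2 change -2.34 ± 0.33, adjusted p = 6.81e-06). In all of these genes the 6 silica rats lay beyond all 6 air rats.

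Cxcl6, a chemokine that attracts neutrophils, was detected in 6 of 6 silica rats and in 0 of 6 air rats, at least 2.44-fold higher (adjusted p = 6.23e-06). Its adjusted p across the alternatives ran from 4.85e-07 to 0.365, the highest with the background taken from all probes. Dlk1, a ligand related to those of Notch, was detected in 6 of 6 air rats and 0 of 6 silica rats, at least 1.86-fold lower. Other genes with the 6 rats of each group apart were lower with silica by smaller amounts. These were Tef (log2 change -0.86 ± 0.17), the lipoxygenase gene Alox15 (-0.69 ± 0.11), the basement membrane collagen gene Col4a3 (-0.65 ± 0.13), Klf9 (-0.54 ± 0.10), Prickle1 (-0.53 ± 0.10) and the endothelial growth factor gene Vegfa (-0.53 ± 0.15, adjusted p = 0.0168). The call of Vegfa was lost without air replicate 5 (adjusted p = 0.0699) or silica replicate 4 at 3 weeks (0.0589), and its adjusted p across the alternatives ran from 0.000785 to 0.0699.

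At 3 weeks 682 genes were higher and 552 lower with silica (limma, Benjamini-Hochberg), of which 73 and 11 changed at least 1.5-fold. The groups did not overlap in 353 genes that rose and 209 that fell, where chance gives 0.216% of genes. Under median scaling the counts were 574 and 92, and the share of called genes that were higher was 86.2% against 55.3%. The count of genes higher by at least 1.5-fold was 42 with the background from all probes and 31 in the authors' values. The count lower by that fold was 1 in the authors' values, 3 with the background from all probes, 4 without background correction and 6 under median scaling, and 19 without air replicate 4 and 7 without air replicate 5 at 3 weeks.

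Of the 36 gene lists, 19 were called at 3 weeks, 15 higher and 4 lower, and 9 of these calls held with an estimated correlation. Other splits of the same arrays called a median of 8 lists at the preset correlation. Of 100 splits 8 reached the real 19 (adjusted within the week), so chance was not excluded for this count. By the fry test 18 lists were called. The mean of the list moved in the called direction in 6 of 6 silica rats for 17 of the 19 lists. Chemokines rose in 14 of 23 measured genes, with 1 lower and 8 not called (15 and 1 adjusted over the list alone, list adjusted p = 2.16e-08). Cxcl1 rose by log2 1.03 ± 0.20 and the monocyte attractant Ccl2 by 1.03 ± 0.23. Acute phase and secreted innate defence proteins rose in 8 of 20 genes with 12 not called (11 adjusted over the list alone, adjusted p = 1.37e-06), among them Chi3l1 (log2 0.997 ± 0.12) and haptoglobin, Hp (0.67 ± 0.12). Complement rose in 10 of 16 genes with 6 not called (11 adjusted over the list alone, adjusted p = 2.28e-09), with Cfi (0.88 ± 0.20) and C1qc (0.48 ± 0.09). Antigen presentation by MHC class II rose in 7 of 14 genes with 7 not called (8 adjusted over the list alone, adjusted p = 1.93e-06), with Ifi30 (0.51 ± 0.05) and the invariant chain gene Cd74 (0.43 ± 0.08). NADPH oxidase and nitric oxide synthesis rose in 6 of 14 genes with 8 not called (8 adjusted over the list alone, adjusted p = 5.96e-05). Besides Noxo1 its members included Arg1 (0.64 ± 0.09), an arginase that competes for the substrate of nitric oxide synthesis.

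Alveolar macrophage genes rose in 8 of 15 with 7 not called (10 adjusted over the list alone, adjusted p = 4.23e-07), including Atp6v0d2 (log2 1.25 ± 0.18) and the lipid receptor gene Trem2 (0.67 ± 0.13). Surfactant proteins and lipid secretion rose in 8 of 18 genes with 10 not called (10 adjusted over the list alone, adjusted p = 0.000101), including the lamellar body gene Lamp3 (0.40 ± 0.08). Type II pneumocyte genes, which overlap with that list, rose in 6 of 15 with 1 lower and 8 not called (9 and 1 adjusted over the list alone, adjusted p = 0.000489), with Muc1 at 0.47 ± 0.08, but adjusted p = 0.0698 with an estimated correlation. The lysosome list rose in 12 of 27 genes with 1 lower and 14 not called (16 and 1 adjusted over the list alone, adjusted p = 5.59e-08), with adjusted p = 0.0597 with an estimated correlation.

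A further group of lists was called higher at 3 weeks only at the preset correlation. NRF2 targets and antioxidant enzymes had 6 of 26 genes higher, 2 lower and 18 not called (7 and 2 adjusted over the list alone, adjusted p = 0.0135; adjusted p = 0.0805 with an estimated correlation). Mt1 (log2 0.87 ± 0.08) and the mitochondrial superoxide dismutase gene Sod2 (0.75 ± 0.10) led them. IL-1, TNF and NF-kB signalling had 10 of 26 higher, 1 lower and 15 not called (11 and 2 adjusted over the list alone, adjusted p = 0.00301; adjusted p = 0.194 with an estimated correlation), with the decoy receptor gene Il1r2 at 0.84 ± 0.14. Cell cycle and DNA replication had 11 of 31 higher and 20 not called (17 adjusted over the list alone, adjusted p = 6.21e-06; adjusted p = 0.128 with an estimated correlation), with Cks2 at 0.49 ± 0.12. Cholesterol synthesis and uptake had 9 of 19 higher and 10 not called (11 and 1 lower adjusted over the list alone, adjusted p = 6.90e-05; adjusted p = 0.143 with an estimated correlation), with Acat2 at 0.38 ± 0.07. Neutrophil genes had 4 of 14 higher and 10 not called (4 adjusted over the list alone, adjusted p = 0.00822; adjusted p = 0.170 with an estimated correlation). Matrix proteases and inhibitors had 7 of 22 higher, 2 lower and 13 not called (7 and 3 adjusted over the list alone, adjusted p = 0.0363; adjusted p = 0.144 with an estimated correlation). Leaving out silica replicate 1, 2 or 3 at 3 weeks ended that call, with adjusted p over all alternatives from 0.0114 to 0.0747. Monocytes and dendritic cells, with 6 of 14 higher, 3 lower and 5 not called (8 and 3 adjusted over the list alone), were not called (adjusted p = 0.0572; adjusted p = 0.242 with an estimated correlation). They passed under 2 settings and without 1 of 5 arrays, in a range from 0.0287 to 0.315.

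Endothelial cell genes fell in 6 of 16 with 10 not called (12 adjusted over the list alone, adjusted p = 7.54e-07), including the carbonic anhydrase gene Car4 (log2 change -0.34 ± 0.06) and Emcn (-0.28 ± 0.05). Type I pneumocyte genes fell in 5 of 16 with 11 not called (9 adjusted over the list alone, adjusted p = 0.000171), including the water channel gene Aqp5 (-0.17 ± 0.05, adjusted p = 0.0293). Both list calls held with an estimated correlation and under every alternative. Under median scaling the single genes Car4, Emcn and Aqp5 were not called (adjusted p = 0.104, 0.133 and 0.648, each the highest of its range, which began at 2.12e-05, 5.57e-05 and 0.00853). Aqp5 also lost its call without air replicate 1, 3 or 4 or silica replicate 1 or 4 at 3 weeks and with only the arrays of that week.

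T and NK cell genes fell in 4 of 20, with 1 higher and 15 not called (5 and 1 adjusted over the list alone, adjusted p = 0.00576; adjusted p = 0.414 with an estimated correlation), including Klrd1 (log2 change -0.32 ± 0.08). The list mean was lower in 5 of 6 silica rats, and without silica replicate 6 at 3 weeks the adjusted p was 0.0536, the highest of a range that began at 0.000416. The fry test did not call the list (adjusted p = 0.0661), nor did its mean pass by the exact permutation test over rats (adjusted p = 0.102). Interferon response genes were called lower as a list with 1 of 25 lower and 24 not called (0 adjusted over the list alone, adjusted p = 0.0309; adjusted p = 0.465 with an estimated correlation). That call was lost with array weights (adjusted p = 0.0634) and without silica replicate 3, 4 or 6 at 3 weeks (0.124, 0.0764 and 0.0536), within a range from 0.00311 to 0.124, and by fry (0.106). The exact permutation test over rats gave the interferon list an adjusted p of 0.0949. Collagens and matrix proteins were not called (4 of 28 lower, 1 higher and 23 not called, 5 and 1 adjusted over the list alone, adjusted p = 0.131), while Col15a1 (-0.41 ± 0.10) and the fibrillin gene Fbn1 (-0.38 ± 0.08) fell. The calls of Klrd1 and Col15a1 were lost under median scaling (adjusted p = 0.157 and 0.115, the highest of ranges that began at 0.00298 and 0.00142). Of the circadian clock genes 3 of 12 rose, 2 fell and 7 were not called (3 and 2 adjusted over the list alone, list adjusted p = 0.938). Cry1 (0.56 ± 0.10) and Nfil3 (0.43 ± 0.09) rose, while Nr1d1 and Tef fell as given above.

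**Figure D2:**
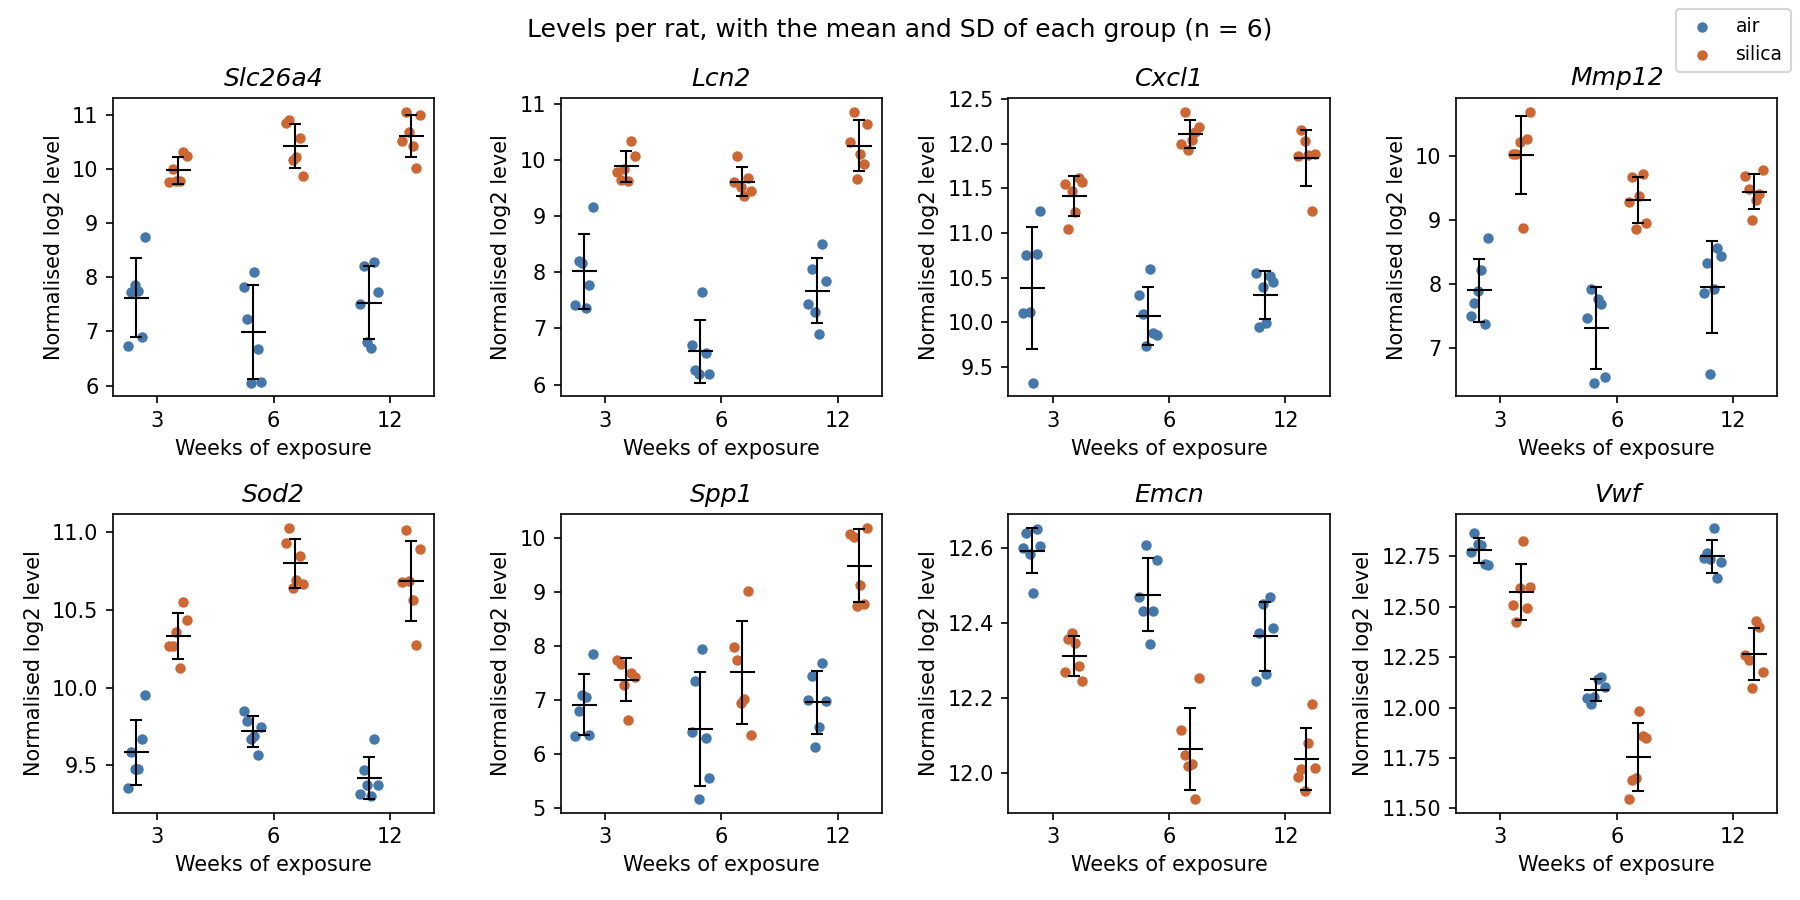
Normalised log2 level (vertical) of 8 genes in each rat by weeks of exposure (horizontal), air and silica, with the mean and SD of each group (n = 6), genes chosen after their values were seen. Every silica rat lay above every air rat of its week for Slc26a4, Lcn2 and Mmp12, with a rise of Slc26a4 of log2 2.36, 3.44 and 3.08 at 3, 6 and 12 weeks, and Spp1 passed the test at 12 weeks (2.53).

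Slc26a4 and Lcn2 were also among the largest rises after 6 weeks of silica. Slc26a4 rose 10.8-fold (log2 3.44 ± 0.32, SE, n = 6 per group, adjusted p = 9.67e-10), Lcn2 8.14-fold (3.03 ± 0.27), Rnase9 6.33-fold (2.66 ± 0.10) and Noxo1 5.04-fold (2.33 ± 0.17). The neutrophil attractant Cxcl1 rose 4.10-fold (2.03 ± 0.20), Mmp12 4.01-fold (2.005 ± 0.29) and Tmem45b 3.91-fold (1.97 ± 0.11). Cxcl6 was detected in 6 of 6 silica rats and 0 of 6 air rats, at least 11.2-fold higher. Nr1d1 was 6.23-fold lower (log2 change -2.64 ± 0.33, adjusted p = 2.57e-07).

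Dlk1 was again detected in air rats alone, at least 1.997-fold lower with silica. The other largest falls with no overlap were those of Alox15 (log2 change -0.72 ± 0.11), Igfbpl1 (-0.69 ± 0.08), Tdrp (-0.67 ± 0.09), the G-protein regulator Rgs7 (-0.65 ± 0.10), Acoxl (-0.62 ± 0.11) and the adrenergic receptor gene Adra1b (-0.59 ± 0.09).

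At 6 weeks 799 genes were higher and 772 lower, of which 117 and 15 changed at least 1.5-fold. The groups did not overlap in 469 genes that rose and 422 that fell, where chance gives 0.216%. Under median scaling the counts were 487 and 205, and the share that were higher was 70.4% against 50.9%. At least 1.5-fold, 77 genes were higher with the background from all probes, and 61 in the authors' values. The count lower by that fold was 2 in the authors' values, 5 with the background from all probes, 8 under median scaling and 9 without background correction.

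At this week 20 lists were called, 15 higher and 5 lower, and 13 calls held with an estimated correlation (25 lists by fry). Other splits of the same arrays called a median of 12 lists at the preset correlation. Of 100 splits 6 reached the real 22 (adjusted within the week), so chance was not excluded for this count. The list mean moved in the called direction in 6 of 6 silica rats for all 20 lists. Antigen presentation by MHC class II rose in 10 of 14 genes with 1 lower and 3 not called (12 and 1 adjusted over the list alone, adjusted p = 1.75e-12), including Ifi30 (log2 0.60 ± 0.05). Chemokines rose in 14 of 23 with 1 lower and 8 not called (16 and 1 adjusted over the list alone, adjusted p = 9.02e-11), including Ccl2 (1.76 ± 0.23) and Cxcl2 (1.61 ± 0.18). The lysosome list rose in 16 of 27 with 1 lower and 10 not called (19 and 1 adjusted over the list alone, adjusted p = 3.38e-12), including the endopeptidase gene Lgmn (0.61 ± 0.08). Acute phase and secreted innate defence proteins rose in 7 of 20 with 13 not called (8 adjusted over the list alone, adjusted p = 1.03e-06). Complement rose in 9 of 16 with 7 not called (9 adjusted over the list alone, adjusted p = 1.30e-05). NADPH oxidase and nitric oxide synthesis rose in 7 of 14 with 7 not called (8 and 1 lower adjusted over the list alone, adjusted p = 5.75e-06). NRF2 targets and antioxidant enzymes rose in 8 of 26 with 1 lower and 17 not called (9 and 2 adjusted over the list alone, adjusted p = 0.000919), including the peroxiredoxin gene Prdx5 (0.61 ± 0.09).

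Surfactant proteins and lipid secretion rose in 11 of 18 genes with 7 not called (11 adjusted over the list alone, adjusted p = 2.28e-07), including the phospholipase gene Pla2g1b (log2 0.53 ± 0.09). Type II pneumocyte genes rose in 9 of 15 with 6 not called (9 adjusted over the list alone, adjusted p = 5.60e-06). Alveolar macrophage genes rose in 9 of 15 with 6 not called (9 and 1 lower adjusted over the list alone, adjusted p = 4.20e-07). Neutrophil genes rose in 6 of 14 with 8 not called (7 adjusted over the list alone, adjusted p = 3.26e-05), including the calprotectin subunit gene S100a8 (0.74 ± 0.14).

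IL-1, TNF and NF-kB signalling rose in 10 of 26 genes with 1 lower and 15 not called (10 and 1 adjusted over the list alone, adjusted p = 3.26e-05), including Il1a (log2 0.65 ± 0.09) and the growth factor gene Csf2 (0.67 ± 0.09), with adjusted p = 0.0698 with an estimated correlation. Cell cycle and DNA replication rose in 14 of 31 with 17 not called (16 adjusted over the list alone, adjusted p = 5.59e-08), including the ribonucleotide reductase gene Rrm2 (0.74 ± 0.10) and Cks2 (0.73 ± 0.12), with adjusted p = 0.0616 with an estimated correlation. Cholesterol synthesis and uptake rose in 9 of 19 with 1 lower and 9 not called (9 and 1 adjusted over the list alone, adjusted p = 5.46e-05), including Fdps (0.46 ± 0.07), with adjusted p = 0.137 with an estimated correlation. Monocytes and dendritic cells were called higher with 5 of 14 higher, 3 lower and 6 not called (6 and 3 adjusted over the list alone, adjusted p = 0.0332; adjusted p = 0.183 with an estimated correlation). That call was lost under 4 settings, the background from all probes among them (adjusted p = 0.0954), and without air replicate 5 at 6 weeks, within a range from 0.0145 to 0.0954. Matrix proteases and inhibitors had 6 of 22 higher, 3 lower and 13 not called (7 and 3 adjusted over the list alone) and missed the threshold (adjusted p = 0.0517; adjusted p = 0.170 with an estimated correlation). They passed it under 7 settings and without 1 of 13 arrays, in a range from 0.0243 to 0.129.

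Endothelial cell genes fell in 11 of 16 with 5 not called (13 adjusted over the list alone, adjusted p = 5.59e-08), including Emcn (log2 change -0.41 ± 0.05) and the von Willebrand factor gene Vwf (-0.33 ± 0.07). Type I pneumocyte genes fell in 6 of 16 with 10 not called (11 adjusted over the list alone, adjusted p = 5.15e-05), including Igfbp2 (-0.54 ± 0.12) and Ager (-0.20 ± 0.04). Ager was not called under median scaling (adjusted p = 0.152, the highest of a range that began at 4.64e-06). T and NK cell genes fell in 10 of 20 with 1 higher and 9 not called (13 and 1 adjusted over the list alone, adjusted p = 0.000292; adjusted p = 0.248 with an estimated correlation). The granzyme gene Gzma (log2 change -0.35 ± 0.08) and Cd8a (-0.36 ± 0.09) were among them. Interferon response genes fell as a list with 3 of 25 lower and 22 not called (3 adjusted over the list alone, adjusted p = 0.00661; adjusted p = 0.340 with an estimated correlation). Collagens and matrix proteins fell as a list with 7 of 28 lower, 1 higher and 20 not called (7 and 2 adjusted over the list alone, adjusted p = 0.0139; adjusted p = 0.183 with an estimated correlation), including Col15a1 (-0.51 ± 0.10). Under median scaling the adjusted p of the collagens and matrix proteins was 0.0542, the highest of a range that began at 0.00313. By the exact permutation test over rats their adjusted p was 0.0859.

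Circadian clock genes moved both ways at 6 weeks, with 4 of 12 higher, 2 lower and 6 not called (4 and 3 adjusted over the list alone, list adjusted p = 0.256). Cry1 (log2 0.82 ± 0.10) and Nfil3 (0.55 ± 0.09) rose. Tef fell (log2 change -0.60 ± 0.17, adjusted p = 0.0135), a call that median scaling ended (adjusted p = 0.0888, the highest of a range that began at 0.00248).

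After 12 weeks of silica Spp1, which encodes the matrix phosphoprotein osteopontin, joined the genes with the largest rises. It rose 5.78-fold (log2 2.53 ± 0.40, SE, n = 6 per group, adjusted p = 1.28e-05), beside Slc26a4 at 8.46-fold (3.08 ± 0.32), Lcn2 at 6.01-fold (2.59 ± 0.27) and Retnla at 4.56-fold (2.19 ± 0.25). Rnase9 rose 4.16-fold (2.06 ± 0.10), Noxo1 3.96-fold (1.99 ± 0.17) and Ceacam4 3.85-fold (1.95 ± 0.08). Cxcl6 was detected in 6 of 6 silica rats and 0 of 6 air rats, at least 4.88-fold higher. Nr1d1 was 4.73-fold lower (log2 change -2.24 ± 0.33, adjusted p = 3.80e-06).

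Dlk1 was detected in air rats alone and was at least 3.05-fold lower with silica. Other large falls with no overlap included those of the natural killer receptor gene Ly49s4 (log2 change -0.89 ± 0.10), Alox15 (-0.87 ± 0.11), Col4a3 (-0.68 ± 0.13), Rgs7 (-0.60 ± 0.10) and the transcription factor gene Pou2f3 (-0.60 ± 0.10).

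At 12 weeks 1061 genes were higher and 1289 lower, of which 145 and 18 changed at least 1.5-fold. The groups did not overlap in 510 genes that rose and 524 that fell, where chance gives 0.216%. Under median scaling the counts were 604 and 1255, and the share that were higher was 32.5% against 45.1%. At least 1.5-fold, 92 genes were higher with the background from all probes and 73 in the authors' values. The count lower by that fold was 3 in the authors' values, 7 without background correction, 42 under median scaling and 10 without silica replicate 2 at 12 weeks.

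At this week 19 lists were called, 16 higher and 3 lower, and 12 calls held with an estimated correlation (22 lists by fry). Other splits of the same arrays called a median of 7 lists at the preset correlation. Of 100 splits 11 reached the real 19 (adjusted within the week), so chance was not excluded for this count. The list mean moved in the called direction in 6 of 6 silica rats for 17 of the 19 lists and in 5 of 6 for cell cycle and type I pneumocyte genes. Chemokines rose in 16 of 23 genes with 1 lower and 6 not called (17 and 1 adjusted over the list alone, adjusted p = 1.75e-12), including Cxcl11 (log2 1.88 ± 0.23) and Ccl2 (1.68 ± 0.23). Antigen presentation by MHC class II rose in 10 of 14 with 1 lower and 3 not called (11 and 1 adjusted over the list alone, adjusted p = 6.12e-11), including RT1-Db1 (0.82 ± 0.11). Complement rose in 11 of 16 with 2 lower and 3 not called (11 and 2 adjusted over the list alone, adjusted p = 1.36e-07), including Cfi (1.24 ± 0.20) and C1qa (0.69 ± 0.09). Acute phase and secreted innate defence proteins rose in 10 of 20 with 10 not called (13 adjusted over the list alone, adjusted p = 1.07e-07), including Chi3l1 (1.32 ± 0.12) and the lung collectin gene Sftpd (0.76 ± 0.14). The lysosome list rose in 18 of 27 with 1 lower and 8 not called (18 and 1 adjusted over the list alone, adjusted p = 6.12e-11). NRF2 targets and antioxidant enzymes rose in 9 of 26 with 3 lower and 14 not called (9 and 3 adjusted over the list alone, adjusted p = 0.000868), including Sod2 (1.26 ± 0.10) and the haem oxygenase gene Hmox1 (0.82 ± 0.10). NADPH oxidase and nitric oxide synthesis rose in 7 of 14 with 2 lower and 5 not called (7 and 2 adjusted over the list alone, adjusted p = 0.00177).

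Matrix proteases and inhibitors rose in 9 of 22 genes with 2 lower and 11 not called (10 and 2 adjusted over the list alone, adjusted p = 0.000398), a call that held with an estimated correlation. They included the cathepsin gene Ctsk (log2 1.02 ± 0.19) and Mmp7, which was detected in 6 of 6 silica rats and 0 of 6 air rats, at least 2.05-fold higher. Surfactant proteins and lipid secretion rose in 11 of 18 with 7 not called (11 adjusted over the list alone, adjusted p = 1.03e-06), including Lamp3 (0.52 ± 0.08). Type II pneumocyte genes rose in 8 of 15 with 7 not called (9 adjusted over the list alone, adjusted p = 2.63e-05). Alveolar macrophage genes rose in 8 of 15 with 7 not called (8 adjusted over the list alone, adjusted p = 7.35e-06; adjusted p = 0.0799 with an estimated correlation). Neutrophil genes rose in 7 of 14 with 7 not called (7 adjusted over the list alone, adjusted p = 0.00153; adjusted p = 0.102 with an estimated correlation), including S100a8 (0.96 ± 0.14) and Il1r2 (1.35 ± 0.14). Monocytes and dendritic cells rose in 8 of 14 with 2 lower and 4 not called (8 and 2 adjusted over the list alone, adjusted p = 0.00374; adjusted p = 0.0760 with an estimated correlation), including the lipopolysaccharide co-receptor gene Cd14 (0.68 ± 0.08). IL-1, TNF and NF-kB signalling rose in 15 of 26 with 2 lower and 9 not called (15 and 2 adjusted over the list alone, adjusted p = 2.02e-05; adjusted p = 0.0632 with an estimated correlation). Cell cycle and DNA replication rose in 14 of 31 with 2 lower and 15 not called (16 and 2 adjusted over the list alone, adjusted p = 2.02e-05; adjusted p = 0.148 with an estimated correlation). Cholesterol synthesis and uptake rose in 7 of 19 with 1 lower and 11 not called (10 and 1 adjusted over the list alone, adjusted p = 0.000206; adjusted p = 0.170 with an estimated correlation).

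Endothelial cell genes fell in 11 of 16 with 5 not called (11 adjusted over the list alone, adjusted p = 3.97e-06), including Vwf (log2 change -0.48 ± 0.07) and Egfl7 (-0.46 ± 0.07). Type I pneumocyte genes fell in 8 of 16 with 8 not called (8 adjusted over the list alone, adjusted p = 0.00147), including the chloride channel gene Clic5 (-0.41 ± 0.05). By the exact permutation test over rats the mean of the type I list did not pass the threshold (p = 0.0823, adjusted p = 0.122). T and NK cell genes fell in 9 of 20 with 1 higher and 10 not called (10 and 1 adjusted over the list alone, adjusted p = 0.00158; adjusted p = 0.335 with an estimated correlation). The perforin gene Prf1 (log2 change -0.52 ± 0.09) and Klrb1a (-0.46 ± 0.09) were among them. Interferon response genes were not called as a list (6 of 25 higher and 19 not called, 4 adjusted over the list alone, adjusted p = 0.131). They passed without silica replicate 1 at 12 weeks (adjusted p = 0.0193, in a range up to 0.406). Collagens and matrix proteins were not called either (1 of 28 higher, 7 lower and 20 not called, 1 and 8 adjusted over the list alone, adjusted p = 0.155), with Spp1 the member that rose and Col6a1 (-0.27 ± 0.06) among those that fell. The airway oxidase gene Cyp4b1 fell (-0.41 ± 0.06), while the xenobiotic and airway metabolism list was not called. Circadian clock genes again moved both ways, with 4 of 12 higher, 2 lower and 6 not called (6 and 2 adjusted over the list alone, list adjusted p = 0.143). Cry1 (0.67 ± 0.10) and Nfil3 (0.47 ± 0.09) rose and Tef fell (-0.60 ± 0.17, adjusted p = 0.0108), a call that the background from all probes ended (adjusted p = 0.0536, the highest of a range that began at 0.000749).

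**Figure D3:**
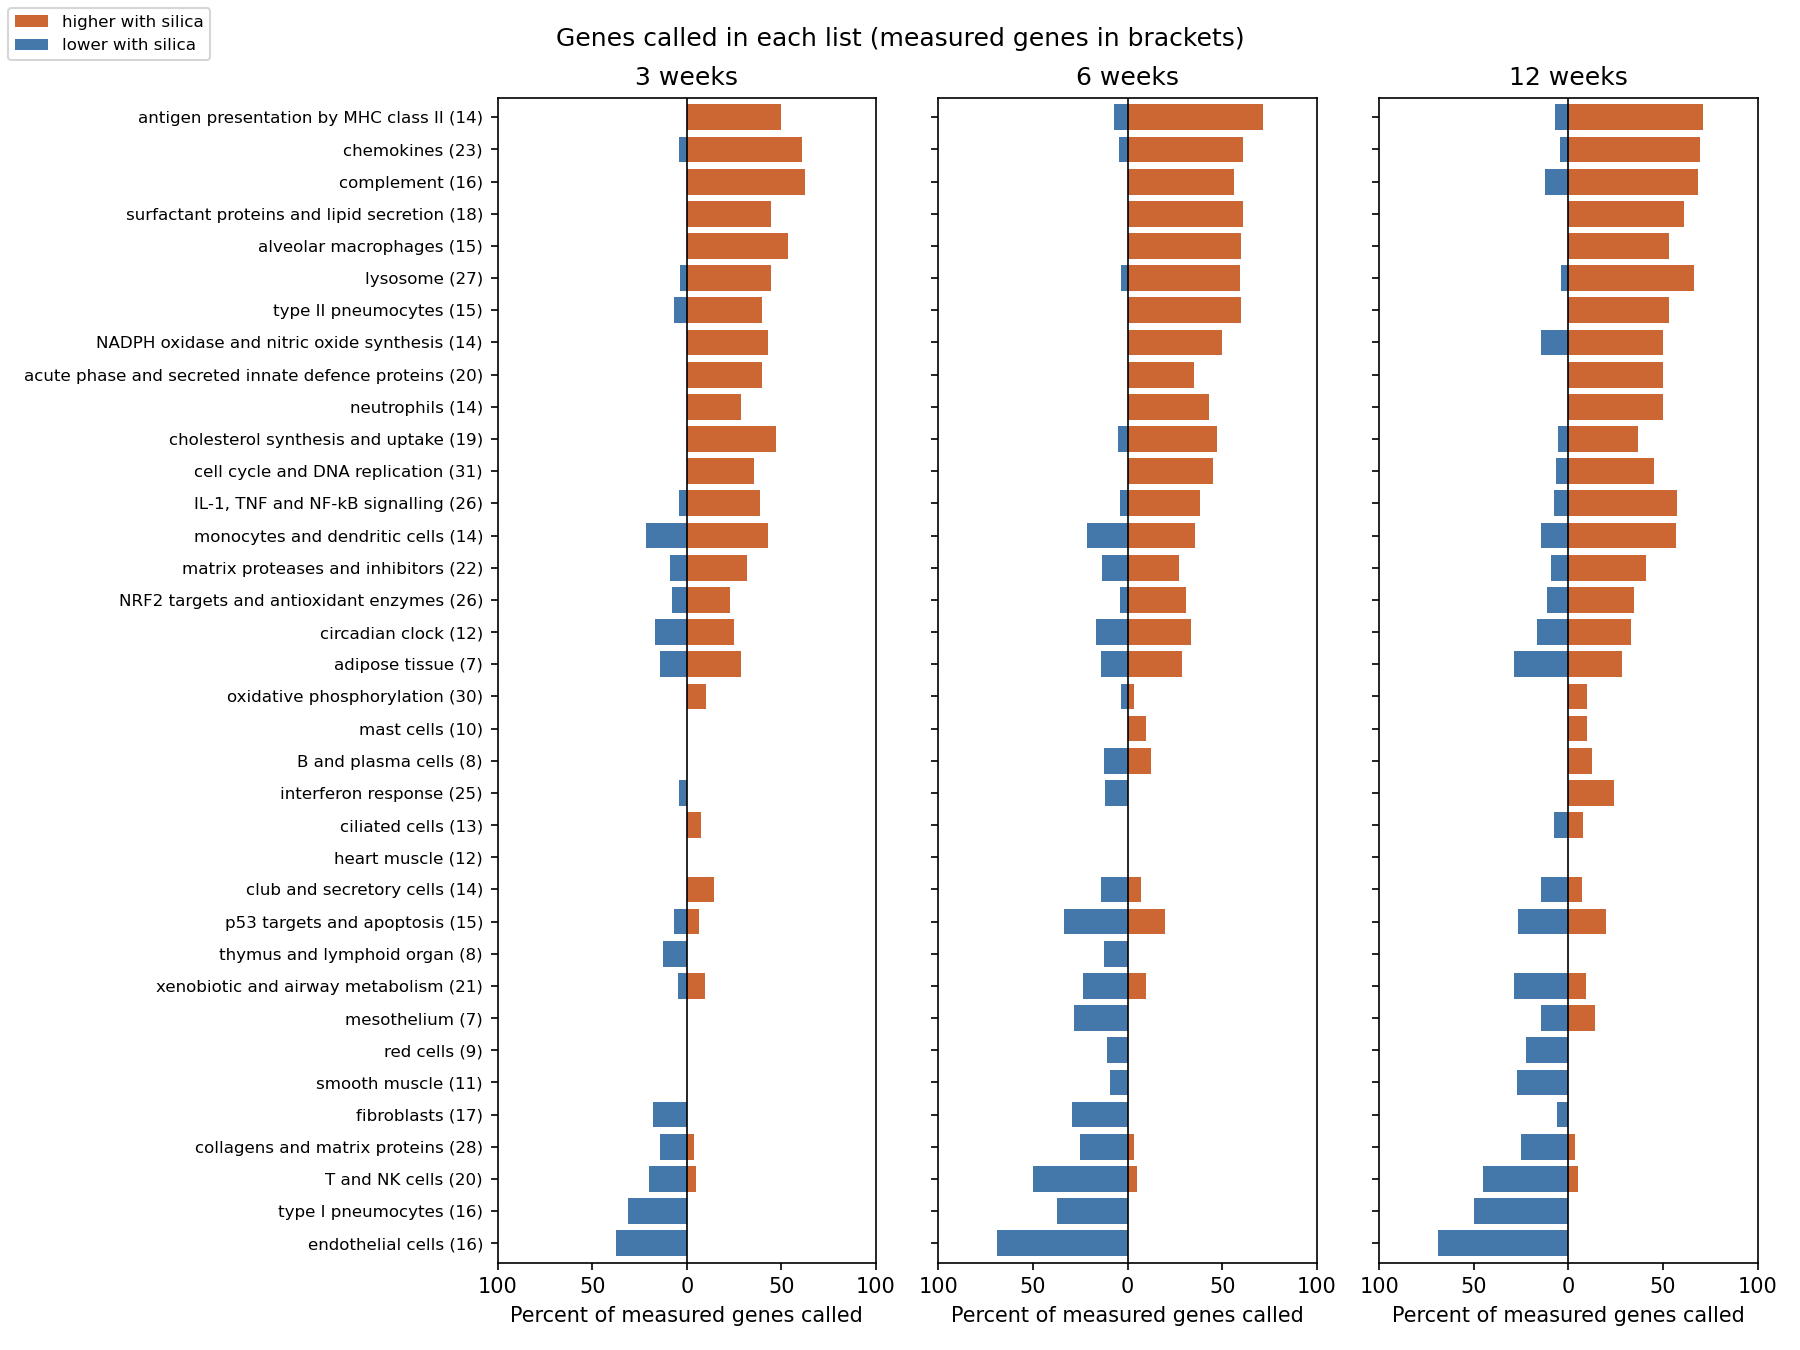
Percent of the measured genes of each of the 36 lists (vertical, measured genes in brackets) that were called higher or lower with silica (horizontal, bars to the right and left of 0) at 3, 6 and 12 weeks. Antigen presentation by MHC class II reached 10 of 14 genes higher at 6 and 12 weeks, and endothelial cells 11 of 16 genes lower.

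Clock genes also differed among rats of 1 group, in the order of the rat numbers in the labels, a relation examined after it had been seen. Over the 36 rats, centred on their group means, Nr1d1 rose with the rat number (r = 0.766, rho = 0.791, permutation p = 1e-05 for each, the smallest these permutations can give, Benjamini-Hochberg adjusted 3.5e-05 and 7e-05 over 7 relations, r = 0.702 without the 2 rats farthest from the median). Cry1 fell with it (r = -0.708, rho = -0.678, permutation p = 2e-05 and 6e-05, adjusted 4.67e-05 and 0.00014, r = -0.663 without the 2 farthest). Within the groups r of Nr1d1 was 0.809 and 0.862 in air and silica at 3 weeks (exact p = 0.0583 and 0.0194). It was 0.777 and 0.926 at 6 weeks (exact p = 0.0889 and 0.00139), and 0.559 and 0.851 at 12 weeks (exact p = 0.233 and 0.0361). The rats of each silica group carried lower numbers than the air rats of their week, except that at 6 weeks silica replicates 5 and 6 carried higher ones.

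**Figure D4:**
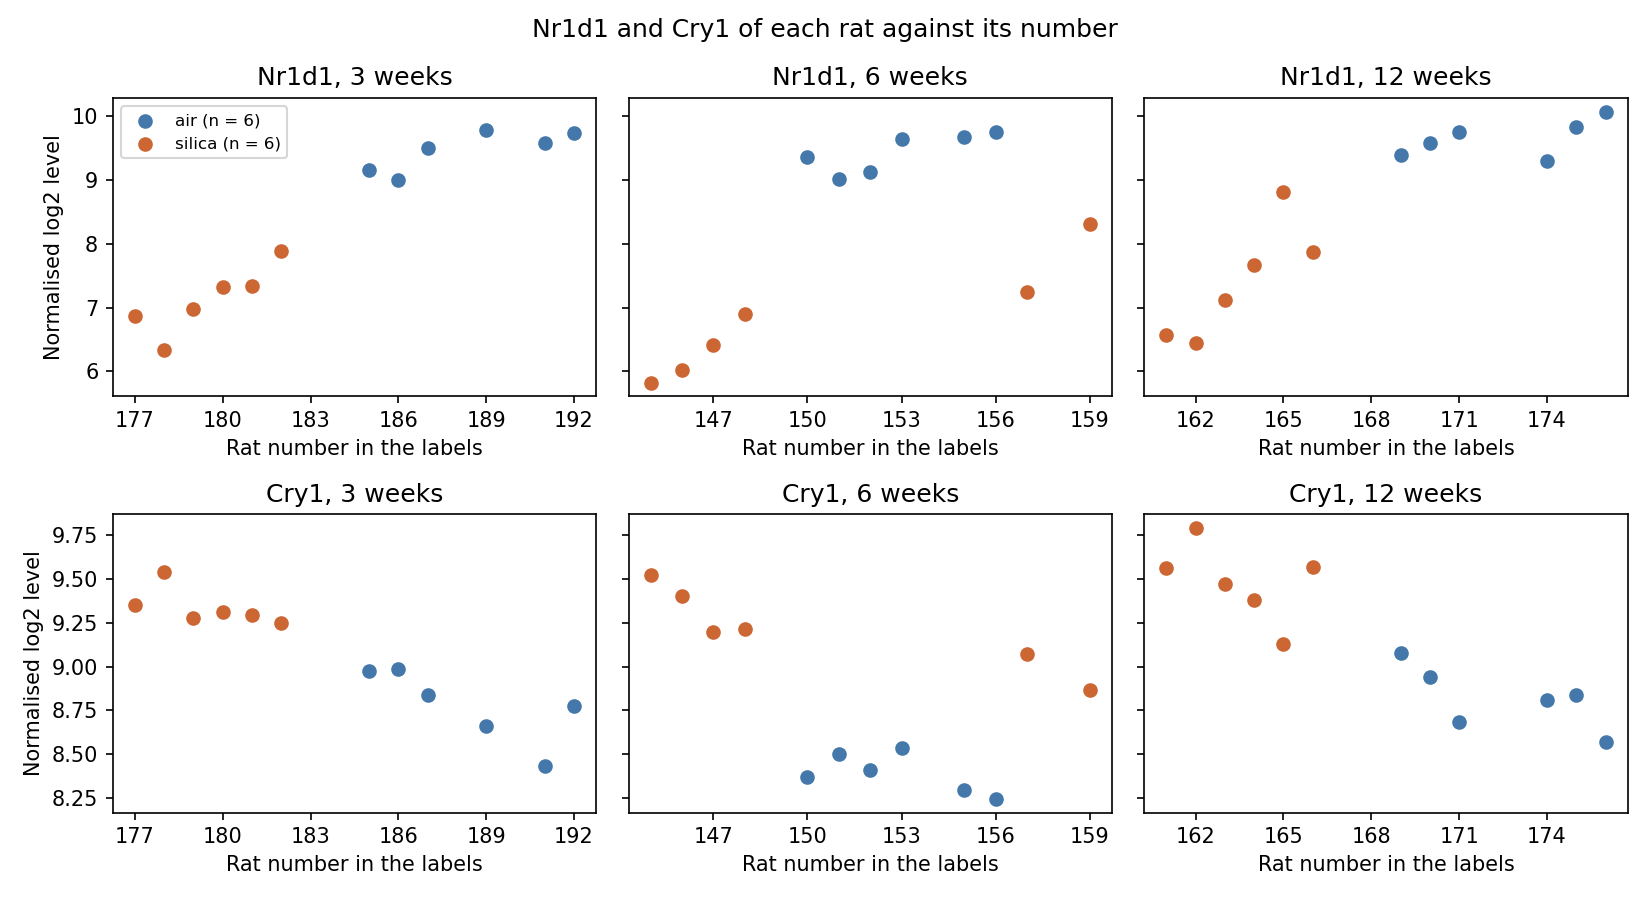
Normalised log2 level of Nr1d1 and Cry1 (vertical) against the number of each rat (horizontal) at 3, 6 and 12 weeks, 1 point per rat, air and silica (n = 6 each). Nr1d1 lay higher and Cry1 lower in rats with higher numbers (r = 0.766 and -0.708 over 36 rats centred on group means), and all silica rats lay below the air rats of their week in Nr1d1.

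At all 3 weeks 596 genes were called in the same direction, 387 higher and 209 lower, where independent lists of these sizes give 7.02 and 6.67. Of these, 57 genes were higher and 4 lower by at least 1.5-fold at every week. In contrast, 15 genes were called in opposite directions at 2 of the weeks. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.723 (rho = 0.579) between 3 and 6 weeks, r = 0.660 (0.481) between 6 and 12 weeks and r = 0.458 (0.267) between 3 and 12 weeks. Under median scaling the count of genes called at all 3 weeks was 289.

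The effect of silica differed between 3 and 12 weeks in 260 genes, with 139 differences positive and 121 negative and 53 of at least 1.5-fold. The count was 68 without silica replicate 2 at 12 weeks, 459 without silica replicate 4 at 12 weeks and 20 with only the arrays of these weeks. Of these genes 198 were called at 12 weeks, and in 193 the effect was larger in size at 12 weeks. Spp1 had the largest positive difference (log2 2.07 ± 0.57, adjusted p = 0.0437), with a change of 0.46 at 3 weeks that was not called. The peroxidase gene Lpo (1.56 ± 0.24, adjusted p = 0.00151) followed, then the interferon-induced chemokine genes Cxcl10 (1.24 ± 0.28, adjusted p = 0.0207) and Cxcl11 (1.19 ± 0.32, adjusted p = 0.0395), and Rftn1 (1.11 ± 0.27, adjusted p = 0.0248). Lpo was detected in 6 of 6 silica rats and 0 of 6 air rats at 12 weeks, at least 3.16-fold higher, so its difference rests partly on levels under detection.

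The largest negative differences were those of Klk6 (-1.56 ± 0.36, adjusted p = 0.0218), Akr1c3 (-1.27 ± 0.31, adjusted p = 0.0279), the basal keratin gene Krt15 (-0.90 ± 0.24, adjusted p = 0.0395), Dmkn (-0.86 ± 0.14, adjusted p = 0.00322) and Dlk1 (-0.78 ± 0.18, adjusted p = 0.0236). Dmkn was detected in 6 of 6 silica rats and 0 of 6 air rats at 3 weeks, at least 2.13-fold higher. Without the arrays air replicate 5 at 3 weeks and silica replicate 3 at 12 weeks, 43 genes differed. Rftn1, Akr1c3, Klk6 and Dlk1 were then not called (adjusted p = 0.0579, 0.0729, 0.0610 and 0.0621, within ranges of 0.0159 to 0.0871, 0.0161 to 0.0729, 0.010005 to 0.0610 and 0.00949 to 0.0621). Spp1 and Krt15 lost their calls too (adjusted p = 0.0558 and 0.113, within ranges of 0.00996 to 0.0895 and 0.0253 to 0.113). Leaving out 1 array ended the call of Spp1 for 14 of the 36 arrays, of Cxcl11 for 12, of Krt15 for 9 and of Akr1c3 and Rftn1 for 3 each. Their highest adjusted p over all alternatives were 0.0895, 0.0901, 0.113, 0.0729 and 0.0871. Cxcl10 reached 0.0617 with only the arrays of these weeks.

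Between 3 and 6 weeks the effect of silica differed in 7 genes, 6 positive and 1 negative. The count was 4 with the stricter filter and with the replicate block, 11 with array weights, and 13 with the background from all probes and without air replicate 1 at 3 weeks. These were Cxcl6 (log2 2.14 ± 0.27, adjusted p = 3.96e-05, with undetected air groups), Rnase9 (0.87 ± 0.14, adjusted p = 0.00133), Stra6l (0.84 ± 0.17, adjusted p = 0.0243), the NF-kB regulator Nfkbiz (0.58 ± 0.10, adjusted p = 0.00612) and Tnfaip2 (0.49 ± 0.10, adjusted p = 0.0296). Dmkn had the negative difference (-0.91 ± 0.14, adjusted p = 0.00116). Enpp2 (0.37 ± 0.07, adjusted p = 0.00973) is outside the rule and was added after its value was seen. Across the alternatives Rnase9, Stra6l, Nfkbiz and Tnfaip2 each lost the call at least once, with highest adjusted p of 0.544 under median scaling, 0.119 with the replicate block, 0.295 and 0.219 without background correction, from lowest values of 0.000233, 0.000580, 0.000382 and 0.000929. Leaving out 1 array ended the call of Stra6l for 6 arrays and of Tnfaip2 for 8.

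Between 6 and 12 weeks 1 gene differed, Lpo (log2 1.56 ± 0.24, adjusted p = 0.00155), while 1165 differed at an unadjusted p under 0.05. The count was 0 with the stricter filter, 21 without silica replicate 4 at 12 weeks, 26 without the 2 arrays apart, 27 with the background from all probes and 47 with array weights. The adjusted p of Lpo ran from 2.63e-06 to 0.0527 across the alternatives, the highest with the background from all probes.

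Lungs without silica were compared between the weeks, and 6878 of 9078 genes differed between the air groups (limma F test, Benjamini-Hochberg). The smallest adjusted p was that of Sim1, with a mean log2 level of 6.19, 4.88 and 4.80 at 3, 6 and 12 weeks (adjusted p = 7.01e-17). Tchp stood at 5.76, 4.68 and 4.92, Ctrl at 6.51, 5.32 and 5.82, Pitpnm1 at 7.03, 6.33 and 7.32, and Ubxn4 at 9.96, 10.68 and 9.92. What else differed between the weeks, array batch included, was not given in the sources used here, so its part cannot be told apart, and silica was compared with air only within a week.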

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

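The tests of clock genes across rat numbers, of the 2 arrays that stood apart and of endothelial genes, and all 100-split counts, were chosen after the result was seen. The 3 other clock tests were written after the fall of Nr1d1 and the rise of Cry1 had been seen but before their own values.

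At all 3 weeks the clock repressor gene Nr1d1 was lower with silica and Cry1 higher. Necropsy of all rats in the order of their numbers was argued against only as the whole cause of the lower Nr1d1 at 6 weeks. Silica replicates 5 and 6 of that week, numbered after the air rats, had Nr1d1 at 7.24 and 8.31. Both values lay under the lowest air rat at 9.004 (7.31 and 7.995 under 8.71 with the background from all probes). Both also lay above every other silica rat of that week, so a part for such an order stays open. At 3 and 12 weeks all silica rats carried lower numbers than the air rats, so those weeks cannot decide. A different time of day of necropsy for silica and air rats stays open: the median log2 changes of the 2 arms of the clock, with 5 genes each, differed by 0.685, 1.04 and 0.463 at 3, 6 and 12 weeks, beyond a limit of 0.3 set before, but by 0.258, 0.307 and 0.209 with the background from all probes, and the rule that both must give the same answer was set after both had been seen. A link to the inflammation of each rat was undecided (r = -0.420 of Nr1d1 with the mean of Lcn2, Cxcl1, Sod2 and Slc26a4 over 18 silica rats, permutation p = 0.124, adjusted 0.145, rho = -0.304, permutation p = 0.258, adjusted 0.301, r = -0.0884 without the 2 farthest rats). A gradient with the rat numbers inside the groups was there (r = 0.766, with Nr1d1 first and Cry1 last of 9078 genes in order of r and the only 2 genes with a called slope, adjusted p = 0.00083 and 0.0197), so a time of necropsy that follows the order inside each group may account for part of the spread, and silica itself remains untested as a cause because time of day and silica cannot be told apart.

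On the first principal component air replicate 5 at 3 weeks (8.72, own group -14.9 to -14.6) and silica replicate 3 at 12 weeks (15.1, own group -14.7 to -8.10) stood far from the other samples of their groups, towards the 6-week arrays. A 6-week lung hybridised with the 6-week set and under a wrong label was argued against. The gap of the nearer array to the 6-week range was 7.63 against an SD of 2.08 in that set. Week and batch cannot be told apart on this component, so the gap cannot decide on a 6-week lung hybridised elsewhere. A loss of detected probes was argued against too, since 51.6% and 52.8% of probes were detected against medians of 51.3% and 52.0% of their groups. This does not settle whether the arrays had little signal, since their mean raw intensities lay under the lowest of their own groups. Hybridisation together with the 6-week arrays stays open, since mean raw intensities of 378 and 402 lay inside the 6-week range of 345 to 427 and under the lowest of their own groups (421 and 407), but 8 of the 22 other 3-week and 12-week arrays lay inside that range too without standing apart. No biological explanation was tested, and the chip of each array was not given in the sources used here.

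Endothelial and type I pneumocyte genes were called lower with silica as lists at all 3 weeks. By the exact permutation test over rats the type I list at 12 weeks did not pass the threshold (p = 0.0823, adjusted p = 0.122). Whether equal dilution of all resident cells by incoming cells was the whole cause could not be decided. The mean of the endothelial list fell beyond that of the fibroblast list by -0.158, -0.151 and -0.135 log2 at 3, 6 and 12 weeks (exact permutation p = 0.0390, 0.00216 and 0.00216). The endothelial list was already called lower in these data and the fibroblast list was not called, so this difference does not test dilution. The type I list was not set against the fibroblast list. A rise of fibroblast genes that offsets dilution stays open, and so does a part for dilution. The fibroblast list itself changed by -0.052, -0.108 and -0.082 (exact permutation adjusted p = 0.454, 0.00557 and 0.240) and smooth muscle by 0.008, -0.111 and -0.122 (0.946, 0.00882 and 0.0631). Type II genes moved above type I genes by 0.342, 0.413 and 0.351 (exact permutation p = 0.00216, 0.00216 and 0.00433). Both lists were already called in these data, so this does not test dilution. Quantile normalisation as the whole cause was argued against, since under median scaling the adjusted p by camera was at most 0.000148 for the endothelial and 0.0148 for the type I list. The setting without background correction kept quantile normalisation, so it cannot bear on this. The mean log2 change under median scaling at 3, 6 and 12 weeks was -0.11, -0.22 and -0.26 for the endothelial list (-0.21, -0.26 and -0.22 with quantile normalisation) and -0.11, -0.16 and -0.16 for the type I list (-0.20, -0.20 and -0.11), beside medians of all genes of 0.0488, 0.0038 and -0.0495 (-0.0012, -0.0162 and -0.0159), while Car4, Emcn and Aqp5 at 3 weeks and Ager at 6 weeks lost their calls (adjusted p = 0.104, 0.133, 0.648 and 0.152) and genes lower at 3 weeks went from 552 to 92. Loss of these cells or lower expression in each cell may both lie behind the fall, and neither was tested.

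In the counts of splits, the real one is included in the 100. Of the 100 splits, 1 gave as many genes as the real 1234 at 3 weeks (highest other 466), 1 as many as 1571 at 6 weeks (859) and 1 as many as 2350 at 12 weeks (822). With at least 1.5-fold it was 1 for 84 genes (highest other 40), 1 for 132 (86) and 1 for 163 (72). By a limit of a share under 0.05 chance was argued against for these counts, as far as 100 splits can tell. All split counts of lists were adjusted within each week, which gives other real counts than the adjustment over all lists and weeks used elsewhere (19, 20 and 19 lists at the preset correlation, 9, 13 and 12 at an estimated one, and 17 called at all 3 weeks). For the lists called at the preset correlation 8, 6 and 11 splits gave as many as the real 19, 22 and 19 lists (highest others 24, 24 and 23, medians of the others 8, 12 and 7), so chance was not excluded. The splits of lists with an estimated correlation and of lists at all 3 weeks were added after that result. Chance was argued against at 6 and 12 weeks, where 1 and 1 splits reached the real 13 and 12 lists with an estimated correlation (highest others 9 and 1). It was argued against too for the 18 lists called at all 3 weeks with this adjustment within the week, which 1 split reached (highest other 7). At 3 weeks 2 splits reached the real 8 lists (adjusted within the week), a share under 0.05, but 1 of them called 11, more than the real one. For genes called at all 3 weeks 1 split reached 596 (highest other 0). Chance was also argued against for differences between weeks, with 1 split for 7 genes between 3 and 6 weeks (highest other 1) and 1 split for 260 genes between 3 and 12 weeks (highest other 2). The splits do not remove the dependence of the 260 on single arrays given above. For the air groups 1 split reached 6878 genes (highest other 3448), and chance was argued against there too. Between 6 and 12 weeks 4 splits reached the single gene, a share under 0.05, but the highest other also had 1, as many as the real one.

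Further levels lay far from the other samples of their group, at 24 of 325 groups tested where chance gives about 1 in 20, or 16.25. Of these, 7 belonged to air replicate 5 at 3 weeks, namely Aqp5 at 10.80, Cd74 at 11.20, Col4a3 at 7.55, Muc1 at 10.31, Rftn1 at 7.90, Vegfa at 9.30 and the first component named above. At 3 weeks the silica rats showed Col15a1 at 9.35 in replicate 5, Cry1 at 9.54 and Lpo at 5.03 in replicate 2, Dlk1 at 4.66 in replicate 1, Hp at 10.002 and Mmp12 at 8.88 in replicate 4, and Nfil3 at 8.48 in replicate 6. At 6 weeks they showed Col15a1 at 9.29 in replicate 6, Rrm2 at 7.85 in replicate 1, Tmem45b at 6.41 in replicate 5 and Tnfaip2 at 5.57 in replicate 2, and air replicate 4 had Lcn2 at 7.65. At 12 weeks the air rats showed Cxcl10 at 5.91 in replicate 1, Cxcl11 at 5.42 in replicate 2, Dmkn at 4.79 in replicate 5 and a second component of -10.4 in replicate 3.

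The effect of silica differed between weeks in tests of the difference itself, for 7 genes between 3 and 6 weeks, 1 between 6 and 12 weeks and 260 between 3 and 12 weeks. With 1 array left out these counts ran from 5 to 13, from 1 to 21 and from 68 to 459. Between 3 and 6 weeks the log2 differences were 2.14 for Cxcl6, 0.87 for Rnase9, 0.84 for Stra6l, 0.58 for Nfkbiz, 0.49 for Tnfaip2 and -0.91 for Dmkn. Between 6 and 12 weeks it was 1.56 for Lpo. Between 3 and 12 weeks named genes had positive differences of 2.07 for Spp1, 1.56 for Lpo, 1.24 for Cxcl10, 1.19 for Cxcl11, 1.11 for Rftn1, 1.03 for Cxcl6, 0.93 for Mmp7, 0.66 for RT1-Db1, 0.63 for Ceacam4, 0.52 for Sod2, 0.51 for Rrm2, 0.45 for RT1-Ba and 0.43 for Cd14. Negative differences were -1.56 for Klk6, -1.27 for Akr1c3, -0.90 for Krt15, -0.86 for Dmkn, -0.78 for Dlk1, -0.70 for Ly49s4, -0.32 for Col6a1 and -0.27 for Clic5. Values of Cxcl6, Lpo, Mmp7, Dmkn and Dlk1 rest partly on levels under detection.

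Among the 3525 detected probes without a gene name here, which the comparisons left out, 178 were higher and 209 lower with silica at 3 weeks, 194 and 178 at 6 weeks, and 252 and 359 at 12 weeks. Their largest called changes, in either direction, had a size of log2 2.42, 2.87 and 2.53.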

How the results depend on the processing

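The background from all probes, leaving out the probes off the detection grid and leaving out the 2 arrays apart were chosen after seeing the data, and the background used in the main counts was itself chosen after counts under both versions had been seen; all other alternatives were set before. Of 144 gene results followed through the alternatives, all called, 122 kept their call under every other setting that gave them a value and 135 with each array left out, and none changed direction. The stricter filter gave a value for 130 of them and the replicate block for 139. Of 108 list results 93 kept their side of the threshold wherever they had a value, 5 lost a call and 10 gained one, apart from the estimated correlation and fry. The called changes were small (median size 0.27 log2 at each week). A stricter threshold leaves fewer calls by construction, and for all other moves below the cause was not tested.

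Without background correction 4, 9 and 7 genes were lower by at least 1.5-fold at 3, 6 and 12 weeks (11, 15 and 18 in the main counts). Median scaling gave 92 genes lower at 3 weeks (6 by at least 1.5-fold), 487 higher and 205 lower at 6 weeks (8 lower by at least 1.5-fold), 604 higher and 42 lower by at least 1.5-fold at 12 weeks, 2 genes that differed between 6 and 12 weeks, 158 between 3 and 12 weeks, and 289 called at all 3 weeks. Of the called genes 624 of 1234, 690 of 1571 and 1706 of 2350 were also called under it, with 3 of the 1234 of opposite sign. The authors' values gave 31, 61 and 73 genes higher and 1, 2 and 3 lower by at least 1.5-fold, and 9 between 6 and 12 weeks. With no detection filter 150 genes differed between 3 and 12 weeks. The stricter filter gave 4 genes between 3 and 6 weeks and 0 between 6 and 12 weeks by limma, where the main filter had 1 and 1165 at an unadjusted p under 0.05. Only the arrays of the weeks compared gave 312 genes lower at 3 weeks (6 by at least 1.5-fold), 6 between 6 and 12 weeks and 20 between 3 and 12 weeks. The intensity trend gave 15 between 6 and 12 weeks. Array weights gave 7 genes lower by at least 1.5-fold at 3 weeks, and 11, 47 and 121 that differed between 3 and 6, 6 and 12, and 3 and 12 weeks. An estimated correlation gave 9, 13 and 12 lists, and fry 18, 25 and 22. By fry 2 lists lost a call, T and NK cells and interferon response at 3 weeks (adjusted p = 0.0661 and 0.106), and 9 gained one. These were monocytes and dendritic cells at 3 weeks (0.00747), circadian clock (0.0027), fibroblasts (0.0136), matrix proteases (0.00213), mesothelium (0.0451) and thymus (0.00375) at 6 weeks, and circadian clock (0.00011), collagens (0.0165) and xenobiotic metabolism (0.0121) at 12 weeks. An adjusted p under 0.01 gave 386 higher and 221 lower at 3 weeks (5 lower by at least 1.5-fold), 391 lower at 6 weeks, and 663 higher and 717 lower at 12 weeks.

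The replicate numbers do not pair rats, so a paired analysis was made only as an alternative. Its blocks each held the silica and the air rat of the same week and replicate number. This replicate block gave 641 higher and 472 lower genes at 3 weeks, 748 and 663 at 6 weeks and 1018 and 1195 at 12 weeks, with 4, 2 and 175 differing between 3 and 6, 6 and 12, and 3 and 12 weeks. It could not give the air comparison, since its blocks lie within the weeks. A chip block was not run, since no chip is given.

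The background from all probes gave 702 higher and 547 lower genes at 3 weeks, 742 and 779 at 6 weeks and 1028 and 1339 at 12 weeks, but 42, 77 and 92 higher by at least 1.5-fold, 3 and 5 lower by that fold at 3 and 6 weeks, and 13 and 27 that differed between 3 and 6 and between 6 and 12 weeks. Without the 2 arrays apart 7 genes were lower by at least 1.5-fold at 3 weeks, and 26 and 43 differed between 6 and 12 and between 3 and 12 weeks.

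Leaving out each array in turn gave 507 to 805 genes higher and 407 to 741 lower at 3 weeks, 668 to 883 and 595 to 912 at 6 weeks, and 863 to 1181 and 1016 to 1423 at 12 weeks. Genes higher by at least 1.5-fold numbered 60 to 77, 109 to 135 and 125 to 169, and lower 7 to 19, 10 to 19 and 10 to 26, with 7 without air replicate 5 and 19 without air replicate 4 at 3 weeks and 10 without silica replicate 2 at 12 weeks. Between 3 and 6 weeks 5 to 13 genes differed (13 without air replicate 1 at 3 weeks), between 6 and 12 weeks 1 to 21 and between 3 and 12 weeks 68 to 459. Between 3 and 12 weeks it was 457, 173 and 88 without air replicates 1, 4 and 5 and 78 and 121 without silica replicates 4 and 6 at 3 weeks, 128, 102, 115, 144 and 146 without air replicates 1, 3, 4, 5 and 6 and 68, 117, 459 and 442 without silica replicates 2, 3, 4 and 5 at 12 weeks. Between 6 and 12 weeks it was 5, 4 and 16 without air replicates 2, 3 and 5 at 3 weeks, 2 without air replicate 6 and 9, 2, 2 and 4 without silica replicates 1, 2, 4 and 6 at 6 weeks, and 2 and 2 without air replicates 2 and 3 and 11, 21, 16 and 2 without silica replicates 3, 4, 5 and 6 at 12 weeks. Genes called at all 3 weeks numbered 510 to 706, genes that differed between the air groups 6722 to 6970, and lists 17 to 20, 19 to 22 and 19 to 20. Signal over background limits what can be seen, since 48.7% to 53.1% of probes were detected on an array.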

Other observations

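The lists of other lung cell types and of tissues that a lung sample can carry along were not called at any week. Counts adjusted over the list alone are in brackets where they differ. Fibroblast genes had 0 of 17 higher and 3, 5 and 1 lower at 3, 6 and 12 weeks (3, 5 and 0; adjusted p = 0.371, 0.0535 and 0.335), the 6-week value passing the threshold under 9 of 13 settings, in a range from 0.0198 to 0.0951. At 12 weeks it passed without silica replicate 3 and without the 2 arrays apart, in a range from 0.0435 to 0.626. Smooth muscle genes had 0, 1 and 3 of 11 lower (0, 3 and 3, with 2 higher at 3 weeks; adjusted p = 0.799, 0.190 and 0.196). Ciliated cell genes had 1, 0 and 1 of 13 higher and 1 lower at 12 weeks (adjusted p = 0.164, 0.831 and 0.0759), and the 12-week value passed under 4 of 13 settings, with adjusted p from 0.0169 to 0.215. Club and secretory cell genes had 2, 1 and 1 of 14 higher and 0, 2 and 2 lower (adjusted p = 0.2499, 0.799 and 0.371), and the 3-week value passed without silica replicate 4 (0.0488, in a range up to 0.648). B and plasma cell genes had 0, 1 and 1 of 8 higher and 0, 1 and 0 lower (0, 2 and 0; adjusted p = 0.7498, 0.493 and 0.867). Mast cell genes had 0, 1 and 1 of 10 higher (adjusted p = 0.618, 0.621 and 0.799). Mesothelium genes had 0, 0 and 1 of 7 higher and 0, 2 and 1 lower (0, 3 and 1; adjusted p = 0.976, 0.330 and 0.938). Red cell genes had 0, 1 and 2 of 9 lower (0, 2 and 2; adjusted p = 0.976, 0.435 and 0.639), heart muscle genes 0 of 12 called (adjusted p = 0.932, 0.230 and 0.571), adipose tissue genes 2, 2 and 2 of 7 higher and 1, 1 and 2 lower (3, 2 and 2; adjusted p = 0.546, 0.974 and 0.984), and thymus and lymphoid organ genes 1, 1 and 0 of 8 lower (1, 0 and 0; adjusted p = 0.897, 0.201 and 0.976).

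Of the pathway lists, oxidative phosphorylation had 3, 1 and 3 of 30 genes higher and 0, 1 and 0 lower (3, 1 and 1 higher and 0 lower; adjusted p = 0.149, 0.360 and 0.511). Under median scaling its adjusted p was 0.000526 at 3 weeks and 0.0458 at 6 weeks, the lowest of ranges that reached 0.489 and 0.610, and leaving out air replicate 3 at 3 weeks also took the 3-week value past the threshold. The p53 targets and apoptosis list had 1, 3 and 3 of 15 higher and 1, 5 and 4 lower (1, 4 and 3 higher, 2, 5 and 4 lower; adjusted p = 0.735, 0.978 and 0.651). Xenobiotic and airway metabolism had 2, 2 and 2 of 21 higher and 1, 5 and 6 lower (1, 7 and 6; adjusted p = 0.976, 0.306 and 0.111), with 0.0466 at 12 weeks without a detection filter, in a range up to 0.223. The median, the mean and the test differed in sign for 11 list results, none of them called. These were mesothelium at 3 and 12 weeks, p53 targets, red cells and thymus at 3 weeks, the circadian clock at 6 and 12 weeks, and B and plasma cells, adipose tissue, collagens and oxidative phosphorylation at 12 weeks.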
